A study of Mus musculus with 12 samples.

How the data were processed

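RNA from 12 mice was measured on dual-colour mouse microarrays, 1 array per mouse, with 4 mice of each of the strains Bl6, CSS1 and CSS2 at postnatal day 14. Each array carried a mouse's RNA in one dye and a reference pool of Bl6 RNA in the other, per the labels. In each strain 2 mice were labelled with Cy5 and 2 with Cy3, and every ratio was turned to sample over reference. The sample labels name hippocampus as the tissue, while the series' design text speaks of brains. That text states that the RNA came from individual mice, so the 4 arrays of a strain were taken as separate animals. CSS1 and CSS2 were taken to be chromosome substitution strains for chromosomes 1 and 2, from their names and general knowledge of such panels, since the labels do not state it.

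The authors deposited the spot intensity of each channel, as mean foreground and median local background, without background subtraction per the file headers. The scanner and the image software are not given in the sources used here. The authors also deposited a table of normalized log2 ratios of the same arrays, whose normalization is not given in the sources used here. Set against the scanner ratios, the authors' values rose with them on 6 of 6 arrays with the sample in Cy5 and ran against them on 6 of 6 arrays with the sample in Cy3, so they are sample over reference. Their strain differences correlated across probes with those computed here at 0.972 for CSS1 and 0.974 for CSS2, with a median size ratio of 1.03 and 1.02 over the 43 and 42 probes with a log2 difference above 0.8, which sets their base at log2. Their column medians were -0.00339, 0.00139, -0.00359 and 0.00585 for Bl6 mice 2, 5, 8 and 11, then -0.000279, -0.00358, -0.00502 and 0.00337 for CSS1 mice 3, 6, 9 and 12, and 0.00493, -0.00155, -0.0000102 and 0.0011 for CSS2 mice 1, 4, 7 and 10. The dye difference had an SD of 0.00548 over probes in that table against 0.223 for the dye effect in the scanner ratios, so a dye bias had been removed probe by probe, by a method that stays unknown. Scale, direction and centring per array were thereby settled from the values.

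Each array has 45220 spots. Gene probes fill 39429 of them, 2200 are control spots, and 3591 belong to 399 unnamed quality probes with 9 spots each, which were kept out of the tests. Background was corrected with normexp (offset 50) and each array was normalized by global loess in limma 3.58.1 under R 4.3.3, with control and quality spots at weight 0 in the loess. The file shows 1 print block, so no print-tip loess could be run. Gene probes were kept when their mean log2 intensity exceeded 6.23, the 95th percentile of 1580 spots of 3 control probe types at background level, whose role as negative controls was inferred from their values. This left out 190 probes and kept 39239. Gene probes at the scanner limit in the sample's channel numbered 0 to 19 per array and were kept. Those in the reference channel were not counted.

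Of the gene probes, 32431 had 1 gene symbol in the platform annotation, 0 had several and 6998 had none. Of the kept probes, 28427 matched a current symbol of the GRCm38.p6 gene table, 3816 matched through an older symbol, 63 kept the file's symbol and 6933 stayed unnamed. The genome build behind the array is not given in the sources used here, so the gene table served only for names and chromosomes. The brightest kept probe stood for each of 21643 genes, of which 21610 had a chromosome, and 7676 genes had more than 1 kept probe. All genes named here were above background on all arrays of the strains compared.

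limma was fitted to all 12 arrays with strain and dye orientation as terms, moderated with eBayes (8 residual and 3.21 prior degrees of freedom), and adjusted by Benjamini-Hochberg over the kept probes of a comparison at a threshold of 0.05. Differences are given as log2 with the standard error of the fit, and strain means as log2 sample over pool after removal of the fitted dye effect. The 26 gene lists, the rule for the genes named and the tests were set before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 26 lists of a comparison. The rule named, per strain against Bl6, the 10 largest rises and falls past the threshold, the 5 largest each way off the substituted chromosome, up to 4 members of each list past the threshold (or up to 2 by p as values only) and Srp9. For CSS1 against CSS2 it named the 5 largest each way and Srp9, and of genes called the same way in both strains the 5 largest each way by mean. Clone and predicted-gene identifiers were passed over. Shares of called genes per chromosome were tested with Fisher's exact test over the genes tested, two-sided and adjusted over 20 chromosomes, and shares of lower calls with an exact binomial test and Clopper-Pearson 95% intervals.

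The fit was tested on simulated data over 39239 probes with 200 changed probes. For CSS1 against Bl6 it recovered 42% of changes of 0.25, 92% of changes of 0.5, 98% of changes of 1 and 100% of changes of 2 on the log2 scale, with 4.05% false calls. For CSS2 against Bl6 it recovered 48%, 94%, 100% and 100% of these, with 5% false calls. The simulated noise was independent between probes and arrays, so these rates do not cover effects shared by many probes of an array. The number of arrays limits the precision.

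The alternatives were no background correction, median centring, scale normalization between arrays, no intensity filter, the dimmer probes, below the median intensity, left out, no dye term, blocks of 3 consecutive mouse numbers in place of the dye term, only the strains compared, array weights, the authors' values, the mean over a gene's probes, and each mouse left out in turn. Camera with an estimated correlation and chromosome shares over all called probes were planned for the lists and shares. Robust regression was added after the data had been seen. The labels pair no mice, and each block of 3 consecutive numbers held 1 mouse of each strain in one dye orientation. No slide or scan date was used here.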

Results

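Gene expression was measured in 12 mice at postnatal day 14, 4 each of the strains Bl6, CSS1 and CSS2, each against one pool of Bl6 RNA. Bl6 is C57BL/6J. The other strains were taken from their names to be chromosome substitution strains, which carry a single chromosome of a donor strain on the Bl6 background. The title of the series names Srp9 as a febrile seizure susceptibility gene, and the comparisons ask which genes differ between each strain and Bl6 and how Srp9 behaves. The median sample signal ranged from 188 to 408 intensity units per array over a median background of 36 to 42. Between 89.1% and 99.7% of gene probes were above background. The lowest share was in CSS2 mouse 1. The 9 spots of a quality probe varied by a median SD of 0.0322 on the log2 scale within an array, and probes varied by a median SD of 0.0663 between mice. Log ratios of arrays with one dye orientation correlated across probes between 0.168 and 0.7. The highest of these correlations leaves no pair of arrays with the same values.

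In CSS1 against Bl6, the 5 largest falls among the named genes lay on chromosome 1. Stk25, a serine/threonine kinase with roles at the Golgi apparatus and in neuronal polarity, was 3.74-fold lower, at a log2 of -1.90 ± 0.14 (SD, n = 4) in CSS1 and 0.00 ± 0.07 in Bl6 (limma adjusted p = 3.16e-07). The interferon-inducible Mndal and Ifi211 were 2.58-fold and 2.2-fold lower, the pericyte gene Rgs5, a regulator of G protein signalling, was 2.35-fold lower, and the neuronal dynamin Dnm3 was 2.03-fold lower. Myl1, a myosin light chain, was 2.38-fold higher, and Kcnj9, a subunit of G protein-gated inwardly rectifying potassium channels, was 1.98-fold higher, at 0.92 ± 0.06 in CSS1 and -0.07 ± 0.04 in Bl6 (adjusted p = 2.86e-05). Npas2, a clock transcription factor, Rpl31, a ribosomal protein gene, and Cox5b, a subunit of cytochrome c oxidase, also fell, by 0.81, 0.82 and 0.53 on the log2 scale. Rnf152 rose by 0.79, and all of these lie on chromosome 1. Mndal and Ifi211 belong to a family of near-identical genes, and the second Mndal probe had the opposite sign and did not pass, so their values are uncertain. Averaged over their probes, Myl1 was at 0.69 and Mndal at -0.65, both still called.

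Over all 21643 genes, 439 passed in CSS1 against Bl6, 253 higher and 186 lower, and 62 of them differed by more than 0.5 on the log2 scale. Chromosome 1 held 93 of the 439, or 21.2%, against 5.45% of the genes tested (odds ratio 4.98, Fisher's exact adjusted p = 4.34e-29). Of the 93, 50 were lower, or 53.8% (exact 95% interval 43.1 to 64.2%). Of the 346 called genes elsewhere, 39.3% were lower, a smaller share (Fisher's exact p = 0.0133). The count depended on single mice: it was 158, 215 and 256 without Bl6 mouse 2, 5 or 11, and 179 and 270 without CSS1 mouse 3 or 9. It was 117 with median centring, 147 without the dye term, 237 with only these 2 strains in the fit and 1046 with array weights. The share on chromosome 1 passed in each of these fits and was 38.6% without Bl6 mouse 2, 35.8% without CSS1 mouse 3, 41.9% with median centring, 39.5% without the dye term and 13.3% with array weights.

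**Figure D1:**
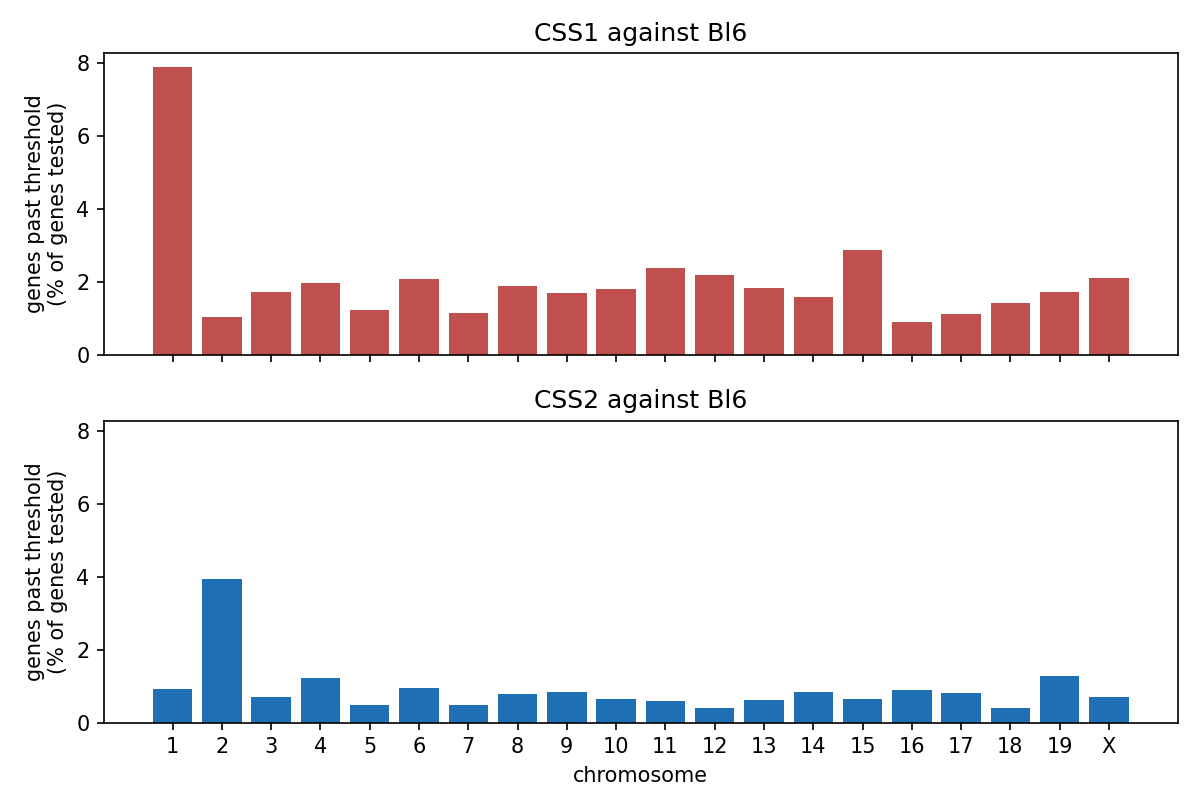
Percent of the genes tested on each chromosome (horizontal axis) that passed the threshold against Bl6 (vertical axis), for CSS1 above and CSS2 below. The highest bar is chromosome 1 in CSS1, at 7.89%, and chromosome 2 in CSS2, at 3.93%.

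Away from chromosome 1, genes of myelinating oligodendrocytes were higher in CSS1. Of the 16 measured members of the myelin list, 9 rose and none fell over all genes tested, and 14 rose when adjusted over the list alone. Mal, a proteolipid of myelin encoded on chromosome 2, had the largest rise among the named genes and was 2.46-fold higher (1.31 ± 0.24 in CSS1, 0.01 ± 0.28 in Bl6, n = 4 each, limma adjusted p = 0.00241). Opalin was 1.85-fold, Cldn11, the tight junction protein of myelin, 1.75-fold, Mobp 1.74-fold, Trf, the iron carrier transferrin, 1.71-fold and Fa2h, which makes hydroxylated myelin lipids, 1.64-fold higher. The list median per mouse was -0.04 ± 0.16 in Bl6 and 0.51 ± 0.08 in CSS1 (SD, n = 4), without overlap (camera adjusted p = 1.05e-20 at the preset and adjusted p = 0.0302 with an estimated correlation). Astrocyte markers had a median difference of 0.24, with 4 of 15 called higher and 9 of 15 adjusted over the list alone (adjusted p = 0.0245 with an estimated correlation). Among them were the connexin gene Gjb6 at 1.55-fold, Ntsr2 at 1.36-fold, S100b at 1.35-fold and Acsl6 at 1.18-fold. Fam107a and the metallothionein Mt1 were 1.93-fold and 1.72-fold higher, though a second Mt1 probe had the opposite sign. Trf and S100b lost the call without Bl6 mouse 2 or 5 or CSS1 mouse 3 or 9 (adjusted p = 0.053 to 0.0767), Ntsr2 without Bl6 mouse 2 or CSS1 mouse 3 (0.0566 and 0.0696), and Acsl6 without Bl6 mouse 2, 5 or 11, CSS1 mouse 3 or 9 or CSS2 mouse 4 or 7 (0.0529 to 0.136). Opalin, Mobp, Fam107a, Mt1, S100b, Ntsr2 and Acsl6 lost it with scale normalization, and the last 4 of these also with median centring (adjusted p = 0.0655 to 0.136 and 0.0563 to 0.413). Cldn11, Mt1 and Acsl6 lost it without the dye term (adjusted p = 0.148, 0.114 and 0.178), and Mobp, Trf, Ntsr2 and Acsl6 with only these 2 strains in the fit (adjusted p = 0.0509, 0.0584, 0.0529 and 0.118).

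Genes of dividing cells were lower in CSS1. Of 22 measured members of the cell division list, 10 fell and none rose, and 16 fell when adjusted over the list alone (median -0.20, camera adjusted p = 1.05e-20 at the preset and adjusted p = 0.0245 with an estimated correlation). Mki67, the proliferation antigen, fell by 0.48 ± 0.09 (SE), Birc5 by 0.42 ± 0.08, the replication factor Mcm3 by 0.37 ± 0.07 and cyclin A2, Ccna2, by 0.34 ± 0.04. Of these 4 genes, Mcm3 lies on chromosome 1. Ccna2 stayed past the threshold with any mouse left out. Mki67 lost the call without any Bl6 mouse or CSS1 mouse 3, 9 or 12 (adjusted p = 0.0522 to 0.103), Birc5 without Bl6 mouse 2 or 11 or CSS1 mouse 3 or 9 (0.0508 to 0.101), and Mcm3 without Bl6 mouse 2 or 11 or any CSS1 mouse (0.0511 to 0.112). The 5 largest falls off chromosome 1 were in genes of other kinds. Dpysl3, a growth cone protein, fell by 0.95 ± 0.16, Fabp7, the fatty acid binding protein of radial glia, by 0.91 ± 0.18, Cxadr, an adhesion receptor, by 0.81 ± 0.14, the tubulin Tubb2b by 0.79 ± 0.08 and Cd24a by 0.67 ± 0.07. Fabp7 lost the call without Bl6 mouse 2, 5 or 11 or CSS1 mouse 3, 9 or 12 (adjusted p = 0.0627 to 0.118), Cxadr without Bl6 mouse 2 or CSS1 mouse 3 (0.0593 and 0.0629) and Dpysl3 without CSS1 mouse 3 (0.0575). Tubb2b lost it with scale normalization, at -0.51 (adjusted p = 0.407), and without the dye term (0.337). Fabp7, Dpysl3, Cxadr, Mki67, Birc5 and Mcm3 also lost it with scale normalization (0.0516 to 0.401), and Fabp7, Mki67, Birc5 and Mcm3 without the dye term (0.053 to 0.334). With only these 2 strains in the fit Fabp7, Dpysl3, Birc5 and Mcm3 lost it (0.0535 to 0.11), and with median centring Birc5 and Mcm3 did (0.0655 and 0.102). Averaged over their probes, Cxadr was at -0.43 and Dpysl3 at -0.54, both still called, and Birc5 at -0.20 without the call (0.09). Of the 50 calls named in CSS1, 26 held with every mouse left out and 16 under all alternatives run on them. One of the other 2 Dpysl3 probes had the opposite sign.

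Of the other lists in CSS1, oxidative phosphorylation had a median difference of 0.08 with 26 of 30 members positive (adjusted p = 0.0245 with an estimated correlation, and adjusted p = 0.0603 with median centring, which ended the call). Its called members went both ways, Sdhc rising by 0.40 and Cox5b falling by 0.53, and both lie on chromosome 1. Sdhc lost the call with median centring (adjusted p = 0.0848). Potassium and HCN channels had a median of 0.07, with Kcnj9, Kcnc1 and Kcnc2 called higher and Kcnk2 lower among 34, and 10 higher and 1 lower adjusted over the list alone (adjusted p = 0.000566 at the preset, adjusted p = 0.158 with an estimated correlation). Kcnc1 and Kcnc2, which carry fast delayed rectifier currents, were 1.46-fold and 1.27-fold higher. The list median was 0.04 without Bl6 mouse 2. Kcnc2 lost the call without Bl6 mouse 2 or CSS1 mouse 3 (adjusted p = 0.054 and 0.0543), Kcnc1 without these or Bl6 mouse 5 or 8 (0.0621 to 0.118), and Kcnk2 without Bl6 mouse 2, 5 or 11 or CSS1 mouse 6, 9 or 12 (0.0506 to 0.106). Kcnk2 also lost it with median centring, without the dye term and with the authors' values (0.825, 0.61 and 0.0519), Kcnc1 without the dye term and with only these 2 strains (0.133 and 0.0929), and Kcnc2 with median centring and scale normalization (0.0875 and 0.104). Interneuron markers had a median of 0.07 with Pvalb at 1.41-fold and Vip at 1.37-fold higher (adjusted p = 0.00621 at the preset, adjusted p = 0.158 with an estimated correlation), and the list lost its call without Bl6 mouse 11, with a median of 0.03 (adjusted p = 0.0973), and had a median of 0.04 without CSS1 mouse 6. Vip lost the call with median centring, scale normalization and without the dye term (adjusted p = 0.0598, 0.0647 and 0.0579), and Pvalb without the dye term (0.677) and without Bl6 mouse 2 or 5 or CSS1 mouse 3 or 6 (0.0669 to 0.103). Microglia markers had a median of 0.07, with Ctss called among 14 (adjusted p = 0.00251, and adjusted p = 0.158 with an estimated correlation). Without Bl6 mouse 11 that list lost its call, at 0.04 (adjusted p = 0.0543), and without CSS1 mouse 6 it was at 0.04, and Ctss lost it without Bl6 mouse 2, 5 or 11 or CSS1 mouse 3 or 9 (0.0563 to 0.0745), with median centring (0.347), with scale normalization (0.193) and without the dye term (0.124). Immediate early genes had a median of 0.10 with none of 22 called (adjusted p = 0.00012, and adjusted p = 0.275 with an estimated correlation). CSS1 mouse 9 had a list median of 0.24 against 0.02 to 0.06 in the other CSS1 mice, and without that mouse the difference was 0.06. The ribosomal protein list, which does not hold Rpl31, had a median of -0.10 with none of its 23 members called (adjusted p = 4.09e-06, and adjusted p = 0.159 with an estimated correlation), and of -0.16 without Bl6 mouse 8.

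In CSS2 against Bl6, the largest rise and the largest fall lay on chromosome 2. Lgr4, a receptor for R-spondins, was 3.99-fold lower, at -1.99 ± 0.10 in CSS2 and 0.01 ± 0.07 in Bl6 (SD, n = 4 each, limma adjusted p = 4.93e-08). Fam171b was 2.49-fold lower and Dnajc10, a disulfide reductase of the endoplasmic reticulum, was 2.13-fold lower. Rbm45, an RNA-binding protein gene, was 3.66-fold higher and Ppp1r16b, a regulatory subunit of protein phosphatase 1, was 3.58-fold higher, and for both the second probe was called in the same direction. Scg5, a chaperone of prohormone convertase, was 2.11-fold and Fam227b 1.9-fold higher. Snhg11 fell by 0.88 ± 0.14 (SE), Ppdpf by 0.70 ± 0.06, the syndecan Sdc4 by 0.68 ± 0.09 and Rbbp9 by 0.66 ± 0.05. Off chromosome 2, Ptar1 was 2.01-fold higher, Phldb1 fell by 0.81 ± 0.13, Riox2 by 0.64 ± 0.04, Actb by 0.57 ± 0.11, the kinase Gsk3b by 0.46 ± 0.06 and Mlxip by 0.44 ± 0.07. Actb lost the call without any Bl6 or CSS2 mouse or CSS1 mouse 3 (adjusted p = 0.0638 to 0.13), Phldb1 without CSS2 mouse 4 (0.0512) and Mlxip without Bl6 mouse 2 (0.0537). For Actb and Gsk3b the CSS2 mice lay near the level of the Bl6 pool, at 0.04 and -0.05, and the Bl6 mice lay above their own pool, at 0.60 and 0.40. With median centring both lost the call (adjusted p = 0.0944 and 0.0697), Actb also with scale normalization (0.053) and without the dye term (0.203), and Snhg11 without the dye term (0.0547). With the mean over a gene's probes, Dnajc10 was at -0.46, Fam171b at -0.78, Riox2 at -0.36, Rbbp9 at -0.35, Mlxip at -0.23 and Fam227b at 1.42, all still called. Of the 34 calls named in CSS2, 22 held with every mouse left out and 18 under all alternatives run on them.

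Over all genes, 225 passed in CSS2 against Bl6, 143 higher and 82 lower, and 54 differed by more than 0.5 on the log2 scale. Chromosome 2 held 76 of the 224 with a chromosome, or 33.9%, against 8.95% of the genes tested (odds ratio 5.39, Fisher's exact adjusted p = 2.46e-24). Of the 76, 36 were lower, or 47.4% (exact 95% interval 35.8 to 59.2%), against 30.4% of the 148 called genes elsewhere (Fisher's exact p = 0.0184). The count was 112, 122 and 148 without Bl6 mouse 2, 5 or 11, and 142, 137 and 108 without CSS2 mouse 1, 4 or 10. It was 119 with median centring, where 74.8% of called genes were higher against 63.6%. With a block of consecutive mouse numbers in place of the dye term 320 genes passed and 48.1% were higher, so the excess of higher calls was not kept. The count was 92 without the dye term and 385 with array weights.

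The myelin list was higher in CSS2 too. Of its 16 members, 8 rose and none fell, and 14 rose adjusted over the list alone. The list median per mouse was 0.56 ± 0.15 in CSS2, above each Bl6 mouse (camera adjusted p = 1.15e-25 at the preset and adjusted p = 0.0163 with an estimated correlation). Mal was 2.33-fold, Opalin 2.03-fold, Cldn11 1.89-fold, Trf 1.84-fold and Fa2h 1.76-fold higher, and Trf lost the call without Bl6 mouse 5 (adjusted p = 0.0526), Opalin with scale normalization (0.0598) and Cldn11 without the dye term (0.113). Oligodendrocyte precursor markers had a median of 0.14, with Bcas1, on chromosome 2, and Olig1 called at 1.36-fold and 1.3-fold among 9, and 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.0163 with an estimated correlation). Astrocyte markers had a median of 0.16 with all 15 positive, of which S100b passed at 1.42-fold and 5 passed adjusted over the list alone (adjusted p = 0.0163 with an estimated correlation). Oxidative phosphorylation had a median of 0.07 with 28 of 30 members positive and none called (adjusted p = 0.0163 with an estimated correlation). Pvalb was 1.51-fold higher, a call lost without Bl6 mouse 2 or 5 or CSS2 mouse 10 (adjusted p = 0.0582 to 0.0632) and, with the largest p, without the dye term (adjusted p = 0.589). Cell division genes had a median of -0.05, with the spindle checkpoint kinase Bub1b, on chromosome 2, called at -0.47 ± 0.05 (SE) among 22 (adjusted p = 0.000509 at the preset, adjusted p = 0.324 with an estimated correlation). Without Bl6 mouse 2 that list lost its call, with a median of -0.02 (adjusted p = 0.0759), and without Bl6 mouse 8 the median was -0.07.

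**Figure D2:**
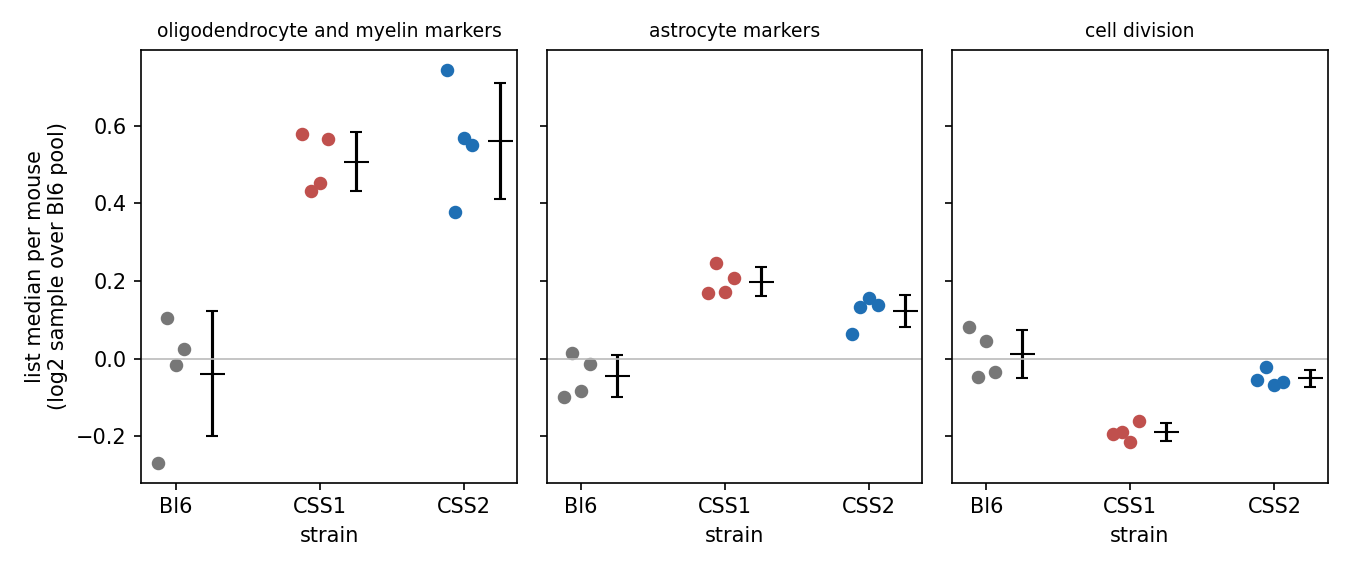
Median log2 sample over Bl6 pool (vertical axis) per mouse for 3 gene lists in the strains Bl6, CSS1 and CSS2 (horizontal axis), with 1 point per mouse and the mean ± SD of 4 mice beside it. Myelin medians lie between 0.43 and 0.58 in CSS1 and between 0.38 and 0.74 in CSS2, above the highest Bl6 value of 0.105, while cell division medians lie between -0.21 and -0.16 in CSS1.

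The remaining lists in CSS2 that passed at the preset correlation lost the call with an estimated one. They were the meningeal list (median -0.14, adjusted p = 0.00548, and adjusted p = 0.0685 with an estimated correlation), immediate early genes (median 0.09, adjusted p = 0.000322 and adjusted p = 0.324), the endoplasmic reticulum list (median 0.05, adjusted p = 0.0402 and adjusted p = 0.354) and the signal recognition particle (median 0.07, adjusted p = 0.0494 and adjusted p = 0.308). Among immediate early genes Nr4a2, on chromosome 2, was called at -0.20 against the list's direction, a call lost without any Bl6 mouse, CSS1 mouse 3 or 12 or CSS2 mouse 1, 7 or 10 (adjusted p = 0.0503 to 0.129). Nr4a2 also lost it with median centring (0.921), the mean over its probes (0.49), scale normalization (0.0645) and the block of mouse numbers (0.051), and without the dye term (0.138). For Nr4a2 the CSS2 mice were at -0.07 and the Bl6 mice at 0.128, above their own pool. Without Bl6 mouse 2 the meningeal list lost its call (adjusted p = 0.0737). The endoplasmic reticulum list lost it without any Bl6 mouse or CSS2 mouse 4 or 10 (0.0508 to 0.188), with a median of 0.02 without CSS2 mouse 10, and the signal recognition particle without Bl6 mouse 2 or 11, CSS1 mouse 3, 6 or 12 or CSS2 mouse 4, 7 or 10 (0.0511 to 0.152), with a median of 0.04 without Bl6 mouse 8. The signal recognition particle list holds 9 measured members with none called, and Srp14 had a log2 difference of 0.26 ± 0.07 (SE, adjusted p = 0.185) in CSS2 and 0.09 ± 0.07 (adjusted p = 0.787) in CSS1. In CSS1 that list had a median of -0.003, a mean of 0.015 and an upward test (adjusted p = 0.535). The sodium channel Scn1a, on chromosome 2, had a difference of -0.17 ± 0.04 in CSS2 (adjusted p = 0.128). Its CSS2 mice were at 0.133 and its Bl6 mice at 0.298, both above the pool.

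Srp9 was read by 2 probes that disagreed in CSS1. At the dimmer probe, Srp9 was 1.33-fold lower in CSS1, at -0.38 ± 0.08 against 0.03 ± 0.08 in Bl6 (SD, n = 4 each), a log2 difference of -0.41 ± 0.05 (SE, limma adjusted p = 0.00196). All 4 CSS1 mice, between -0.50 and -0.32, were below all 4 Bl6 mice, the lowest of which was at -0.06. At the brighter probe, which stands for the gene in counts, CSS1 was at 0.09 ± 0.09 and Bl6 at 0.05 ± 0.04, a difference of 0.05 ± 0.05 (adjusted p = 0.869). The mean of both probes differed by -0.18 (adjusted p = 0.0717). With median centring the dimmer probe kept its difference, -0.39, and lost the call (adjusted p = 0.0666). In CSS2 the differences from Bl6 were 0.04 ± 0.05 at the dimmer probe (adjusted p = 0.89) and 0.05 ± 0.05 at the brighter probe (adjusted p = 0.887). Between CSS1 and CSS2 the dimmer probe differed by -0.45 ± 0.05 (adjusted p = 0.000474), and the brighter probe by 0 ± 0.05, without a call.

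**Figure D3:**
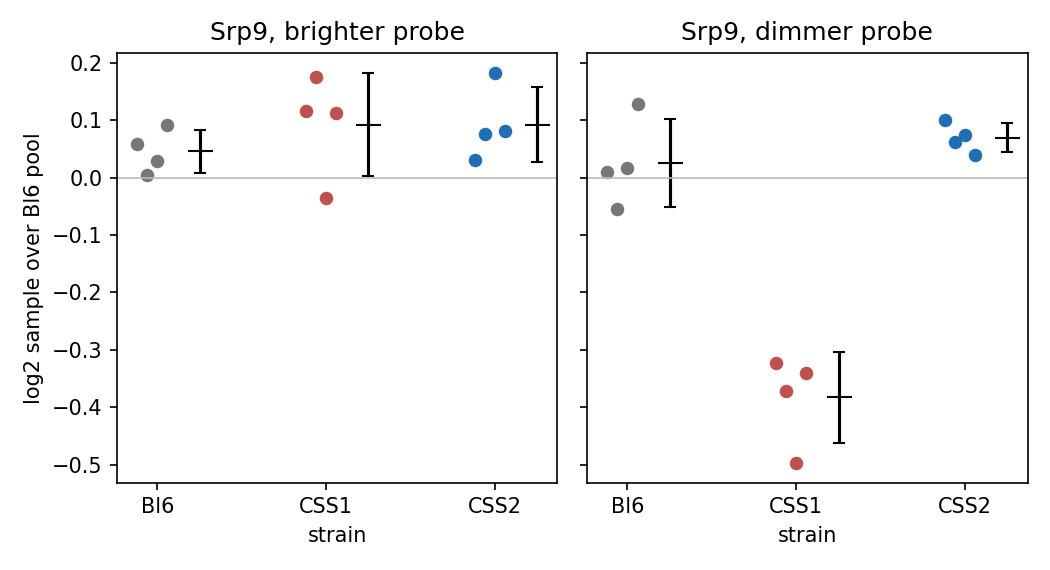
Log2 sample over Bl6 pool (vertical axis) at the brighter and the dimmer probe of Srp9 in the strains Bl6, CSS1 and CSS2 (horizontal axis), with 1 point per mouse and the mean ± SD of 4 mice beside it. At the dimmer probe the CSS1 mice lie between -0.50 and -0.32, below all others, and at the brighter probe the strains overlap.

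In the direct contrast of CSS1 and CSS2, the 10 largest differences named lay on chromosomes 1 and 2. Of 210 genes that passed, 81 were higher and 129 lower in CSS1. Chromosome 1 held 70 and chromosome 2 held 79 of the 209 with a chromosome (odds ratios 9.22 and 6.4, Fisher's exact adjusted p = 3.06e-35 and 3.01e-29). Higher in CSS1 were Lgr4, 4.18-fold, Fam171b, 2.37-fold, Myl1, 2.31-fold, Rnf152, 2.11-fold, and Dnajc10, 2.1-fold. Lower in CSS1 were Stk25, 3.76-fold, Ppp1r16b, 3.7-fold, Rbm45, 3.54-fold, Mndal, 2.67-fold, and Ifi211, 2.25-fold. All 11 probes called and named in this contrast, the dimmer one of Srp9 included, passed under each alternative run on them. The brighter Srp9 probe was not called. Myl1, Ifi211, Mndal and Ppp1r16b were below the median intensity and were not run with the dimmer probes left out. Oligodendrocyte precursor markers were lower in CSS1 than in CSS2, with a median of -0.13 and all 9 members negative (camera adjusted p = 9.54e-07, and adjusted p = 0.0166 with an estimated correlation). Cell division genes had a median of -0.15, with 3 of 22 called lower (adjusted p = 3.17e-12, adjusted p = 0.0921 with an estimated correlation, and fry adjusted p = 0.0147). Potassium and HCN channels had a median of 0.09, with 2 of 34 called higher (adjusted p = 9.54e-07, adjusted p = 0.0921 with an estimated correlation, and fry adjusted p = 0.0147). Ribosomal protein genes had a median of -0.06 (adjusted p = 0.0015, and adjusted p = 0.442 with an estimated correlation), microglia markers 0.10 (adjusted p = 0.000737 and adjusted p = 0.14), erythroid genes 0.27 (adjusted p = 0.0015 and adjusted p = 0.173) and CA1 and CA3 pyramidal cell markers 0.10 (adjusted p = 0.0015 and adjusted p = 0.173). None of these lists passed with fry (fry adjusted p = 0.0713 to 0.301). The total count was 139 without CSS2 mouse 10, 96 with median centring and 113 without the dye term.

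Of the genes called against Bl6, 69 were higher in both strains, 14 were lower in both and 0 went opposite ways. The largest shared rises were Mal, Opalin, Cldn11, Trf and Fa2h, and the largest shared falls were Cd24a, Bub1b, Dpysl5, a growth cone protein, Necab1 and Tm7sf2, an enzyme of sterol synthesis. Dpysl5 fell by 0.39 in CSS1 and by 0.29 in CSS2, and Tm7sf2 by 0.32 and by 0.28. For Necab1 and Tm7sf2 the Bl6 mice, shared by both comparisons, lay above their own pool, at 0.22 and 0.145. CSS1 and CSS2 mice were at -0.075 and -0.151 for Necab1 and at -0.173 and -0.139 for Tm7sf2, so the Bl6 mice make up part of these falls. In CSS2, Cd24a lost the call without Bl6 mouse 2, 5 or 11, CSS1 mouse 3, 6 or 12 or any CSS2 mouse (adjusted p = 0.0547 to 0.147), and Dpysl5 without Bl6 mouse 2, 8 or 11, CSS1 mouse 3 or CSS2 mouse 1, 4 or 10 (0.0595 to 0.126). Necab1 lost it there without Bl6 mouse 2 or 5 or CSS2 mouse 1, 4 or 10 (0.06 to 0.082), and Tm7sf2 without any Bl6 mouse, CSS1 mouse 3, 6 or 9 or CSS2 mouse 1, 7 or 10 (0.0615 to 0.158). In CSS1, Necab1 lost it without Bl6 mouse 2, 5 or 11 or any CSS1 or CSS2 mouse (0.0509 to 0.149), Tm7sf2 without Bl6 mouse 2 or 5 or CSS1 mouse 3, 6 or 9 (0.0514 to 0.0752) and Bub1b without Bl6 mouse 2 (0.0549). With a block of consecutive mouse numbers Dpysl5 and Tm7sf2 lost the call in CSS2 (adjusted p = 0.0521 each). Median centring ended the CSS2 calls of Cd24a, Dpysl5, Necab1 and Tm7sf2 (0.132 to 0.719), and the CSS1 calls of Bub1b, Dpysl5, Necab1 and Tm7sf2 (0.0985 to 0.377). Without the dye term Necab1 lost the call in CSS1 and CSS2 (0.743 and 0.607), and Cd24a, Dpysl5 and Tm7sf2 in CSS2 (0.0741 to 0.0808). Cd24a and Dpysl5 also lost it in CSS2 with scale normalization (0.183 and 0.0588), Cd24a, Tm7sf2 and, in CSS1, Necab1 with only the strains compared (0.0879, 0.0966 and 0.153), and Tm7sf2 in CSS2 with the mean over its probes (0.135). Independent lists of these sizes would share 1.67 higher and 0.705 lower genes. In 20 simulated sets of unchanged strains against shared controls the highest overlap was 0, which sets no useful bound because unchanged strains give few calls. With the Bl6 mice split between the comparisons, 6 to 16 genes were called higher in both and 0 to 2 lower in both, over 4 splits, where independent lists would share at most 0.588 and 0.388. Across genes, which are not independent replicates, the log2 differences of both strains correlated at 0.553, close to the simulated 0.501 from the shared controls alone, and at 0.0596 to 0.354 with split controls. Their covariance was 0.00615 against a simulated 0.00242 from the shared controls alone, and 0.000962 to 0.0045 with split controls. The shared count was 19, 34 and 36 without Bl6 mouse 2, 5 or 11, 34 and 54 without CSS1 mouse 3 or 9, and 48, 39 and 31 without CSS2 mouse 1, 4 or 10.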

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

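The test of the quality probes was chosen after the data had been seen, and the others followed rules set before the data were examined. In 444 sets of 4 mice of a strain, 23, or 5.18%, held a mouse far from the other 3 by Dixon's test, and chance gives about 1 in 20. All values are log2 sample over pool.

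In Bl6, mouse 11 stood apart at Npas2 (-0.119, the others -0.011 to 0.001), Homer1 (0.048, the others -0.109 to -0.1), Lct (-0.074, the others -0.019 to -0.016) and Phldb1 (0.194, the others -0.122 to -0.113).

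In CSS1, mouse 9 had a median of 0.237 over immediate early genes against 0.024 to 0.059 in the others, and stood apart at Islr (-0.031) and Tsix (0.3). Mouse 12 had a median of -0.036 over choroid plexus markers against -0.004 to -0.003, and stood apart at Ctss (0.244) and Vip (0.235), where the others were higher. Mouse 6 stood apart at Ptprz1 (-0.413), Fam171b (0.041), Olig1 (-0.054) and Necab1 (-0.244), and mouse 3 at Rpl8 (-0.036).

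In CSS2, mouse 4 had a median of 0.093 over interneuron markers against 0.035 to 0.036 in the others, and stood apart at Camk2a (0.203). Mouse 7 stood apart at Fam107a (0.179, the others 0.5 to 0.525), Dnm3 (0.142) and Lamp5 (0.017), mouse 10 at Cacna1e (-0.018) and Hbb-bh1 (0.064), and mouse 1 at Rbbp9 (-0.734).

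The response of oligodendrocyte precursor markers differed between the strains, with a median of -0.127 for CSS1 minus CSS2 (camera adjusted p = 0.0166 with an estimated correlation). Among the 399 unnamed quality probes, which enter no comparison above, 31 passed the threshold in CSS1 against Bl6, 17 higher and 14 lower, and 8 passed in CSS2, 4 higher and 4 lower.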

How the results depend on the processing

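Robust regression was chosen after the results were seen, and all other alternatives were set before. Of the values that answer a comparison, 409 kept their direction and call, or stayed within 1.5 times for counts, over the alternatives, 40 moved, 2 reversed, 4 lost a call and 1 gained one. Of the values for single genes and lists, 4410 kept both, 348 lost a call, 110 gained one and 76 reversed. The shares of called genes on chromosome 1 in CSS1 (10.7 to 41.9%) and on chromosome 2 in CSS2 (17 to 49.5%) passed under all alternatives, as did the myelin lists under those run on lists (medians 0.481 to 0.664 and 0.56 to 0.724). With the mean over a gene's probes other calls shrank by over 1.5 times and held: in CSS1 Fam107a was at 0.57, Mt1 at 0.39, Kcnc1 at 0.29 and Dpysl5 at -0.23, and in CSS1 against CSS2 Fam171b at 0.74, Myl1 at 0.64, Dnajc10 at 0.39, Mndal at -0.66 and Srp9 at -0.23. List medians in CSS2 grew with median centring for the signal recognition particle (0.11), the endoplasmic reticulum list (0.09), oxidative phosphorylation (0.11) and cell division (-0.08). Immediate early genes were at 0.16 in CSS2 with the dimmer probes left out and at 0.05 in CSS1 with array weights, and the endoplasmic reticulum list in CSS2 at 0.03 with the mean over probes. Leaving out the intensity filter changed no count. The labels pair no mice, but with a block of 3 consecutive mouse numbers in place of the dye term, which holds 1 mouse of each strain, 449, 320 and 232 genes passed in CSS1, CSS2 and CSS1 against CSS2. Of these, 376, 204 and 184 were also called in the report's setting. The share of higher calls in CSS2 was 48.1% with the block against 63.6%. The signal recognition particle in CSS2 lost its call there (adjusted p = 0.0754), and cytokine genes in CSS1 passed (adjusted p = 0.0358). Signal over background limits the dimmest probes, and the cause of the changes below was not tested, except that fewer probes or arrays entered where stated.

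With an estimated correlation, 8 of the 18 list calls against Bl6 held, and cell division in CSS2 kept its median of -0.048 without the call (adjusted p = 0.324). Of the calls lost there, fry passed potassium and HCN channels and interneuron markers in CSS1 (fry adjusted p = 0.0261 and 0.0457) and meningeal markers in CSS2 (0.0339). It did not pass immediate early genes, ribosomal proteins or microglia in CSS1 (0.0586 to 0.172). In CSS2 it did not pass cell division, immediate early genes, the signal recognition particle or the endoplasmic reticulum list (0.137 to 0.295). Without background correction, CA1 and CA3 markers in CSS2 turned to -0.000198 and the brighter Srp9 probe in CSS1 against CSS2 to 0.000407. With median centring, 117, 119 and 96 genes passed in CSS1, CSS2 and CSS1 against CSS2, of which 116, 109 and 95 were also called in the report's setting, and 31 passed in both strains. There the dimmer Srp9 probe in CSS1 was at -0.39 without the call (adjusted p = 0.0666), the signal recognition particle in CSS1 turned to 0.00825, and in CSS2 GABA genes turned to 0.022, calcium channels to 0.0078, ribosomal proteins to 0.0133 and thalamus, striatum and cortex markers to 0.0224. With scale normalization, dentate markers turned to -0.00588 in CSS1 and -0.013 in CSS2, cell division in CSS2 was at -0.0286 without the call (adjusted p = 0.0725), and microglia and CA1 and CA3 markers in CSS2 were at -0.0195 and -0.0161. With the dimmer probes left out, so that fewer were tested, 135 genes passed in CSS1 against CSS2, and glutamate receptors (-0.0227), sodium channels (0.0402) and heat shock genes (-0.0012) in CSS1 and CA1 and CA3 markers (-0.00535) in CSS2 reversed. Without the dye term 147, 92 and 113 genes passed and 22 in both strains. With only the strains compared, and so fewer arrays, 237 passed in CSS1, 132 in CSS1 against CSS2 and 39 in both strains. Array weights gave 1046 genes in CSS1, 385 in CSS2 and 181 in both, and turned the signal recognition particle (0.0239), calcium channels (0.00624) and endothelial markers (-0.0102) in CSS1 and microglia (-0.00453) and CA1 and CA3 markers (-0.00509) in CSS2. With the authors' values, heat shock genes (-0.0104) and endothelial markers (-0.002) in CSS1 were negative. With the mean over a gene's probes, Srp9 in CSS1 was at -0.181 (adjusted p = 0.0717), calcium channels (0.0162) and endothelial markers (-0.00205) in CSS1 reversed, and so did microglia (-0.00215), dentate (-0.00476), CA1 and CA3 (-0.00124) and thalamus, striatum and cortex markers (0.0000437) and Itgam (-0.0224) in CSS2. Robust regression, run on genes and not on lists, gave 1857, 1068 and 917 genes and 517 in both strains, a lower share of 58.1% on chromosome 1 (exact p = 0.0273), and 0.0313 for the brighter Srp9 probe in CSS1 against CSS2.

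With each mouse left out in turn, 158 to 537 genes passed in CSS1, 108 to 228 in CSS2, 139 to 211 in CSS1 against CSS2 and 19 to 84 in both strains, with the mice named in the report. The lower share on chromosome 2 was 45.2 to 50%, and the brighter Srp9 probe in CSS1 against CSS2 -0.0314 to 0.048. Medians in CSS1 ranged from -0.019 to 0.0381 for the signal recognition particle, -0.00185 to 0.0628 for the endoplasmic reticulum list, -0.0275 to 0.00998 for glutamate receptors, -0.00893 to 0.012 for sodium channels, -0.0399 to 0.0467 for calcium channels, -0.019 to 0.053 for heat shock genes, -0.0116 to 0.00978 for endothelial markers, -0.00241 to 0.044 for thalamus, striatum and cortex markers and -0.0304 to 0.0733 for sex-linked genes. In CSS2 they ranged from -0.0732 to -0.0172 for cell division, whose call was lost without Bl6 mouse 2, -0.00847 to 0.00952 for glutamate receptors, -0.0454 to 0.000297 for potassium and HCN channels, -0.0473 to 0.00796 for calcium channels, -0.0198 to 0.0238 for microglia, -0.0169 to 0.0339 for dentate, -0.0243 to 0.0104 for CA1 and CA3 and -0.0181 to 0.0202 for thalamus, striatum and cortex markers.

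With scale normalization, Fam107a, Opalin, Mobp, Mt1, Ly6c1, Vip, Ntsr2, S100b, Kcnc2, Slco1a4, Ctss, Scn4b, Gabrd, Acsl6, Mcm3, Igfbp2, Birc5, Mki67, Tubb2b, Cxadr, Fabp7 and Dpysl3 lost the call in CSS1. Without the dye term, Cldn11, Mt1, Ly6c1, Kcnc1, Pvalb, Vip, Ctss, Scn4b, Gabrd, Acsl6, Kcnk2, Grin3a, Necab1, Mcm3, Igfbp2, Ptprz1, Birc5, Mki67, Tubb2b and Fabp7 lost the call in CSS1. With only the strains compared, Mobp, Trf, Ly6c1, Kcnc1, Ntsr2, Scn4b, Gabrd, Acsl6, Necab1, Mcm3, Igfbp2, Birc5, Fabp7 and Dpysl3 lost the call in CSS1. With median centring, Mt1, Ly6c1, Vip, Ntsr2, S100b, Sdhc, Kcnc2, Slco1a4, Ctss, Scn4b, Gabrd, Acsl6, Kcnk2, Grin3a, Bub1b, Necab1, Tm7sf2, Mcm3, Igfbp2, Dpysl5 and Birc5 lost the call in CSS1. With the mean over a gene's probes, Acsl6, Grin3a, Igfbp2 and Birc5 lost the call in CSS1. With the authors' values, Kcnk2 lost the call in CSS1.

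With scale normalization, Opalin, Nr4a2, Kcnma1, Dpysl5, Cd24a and Actb lost the call in CSS2. Without the dye term, Cldn11, Pvalb, Nr4a2, Tm7sf2, Kcnma1, Cpne4, Dpysl5, Cd24a, Necab1, Actb and Snhg11 lost the call in CSS2. With median centring, Nr4a2, Tm7sf2, Kcnma1, Cpne4, Dpysl5, Cd24a, Necab1, Gsk3b and Actb lost the call in CSS2. With the block, Nr4a2, Tm7sf2, Cpne4 and Dpysl5 lost the call in CSS2. With the mean over a gene's probes, Nr4a2, Tm7sf2, Kcnma1 and Cpne4 lost the call in CSS2. With only the strains compared, Tm7sf2, Kcnma1, Cpne4 and Cd24a lost the call in CSS2. Without background correction, Kcnma1 lost the call in CSS2. Of the lists, potassium and HCN channels in CSS1 (adjusted p = 0.0609) and meningeal markers in CSS2 (0.0883) lost the call with scale normalization. So did the signal recognition particle and the endoplasmic reticulum list in CSS2 (0.189 and 0.176), which also lost it with the dimmer probes left out (0.0761 and 0.063) and without the dye term (0.0741 each). Oxidative phosphorylation in CSS1 lost it with median centring (0.0603).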

Other observations

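The tests of a single mouse, of a lower share of neurons, of white matter, and of dye bias and a single array for Srp9, and the use of dye-balanced splits in place of all splits, were chosen after the result was seen. The list of immature neuron genes was also drawn up after falls of other such genes had been seen. In CSS1 against Bl6, several neuronal and vascular genes passed as members of lists that did not pass. Grin3a, an NMDA receptor subunit, fell by 0.26 (glutamate receptor list, median 0.00, adjusted p = 0.65), Gabrd, a GABA receptor subunit, rose by 0.24 (GABA list, median 0.04, adjusted p = 0.273) and Scn4b, a sodium channel beta subunit, rose by 0.29. The sodium channel list had a median of -0.009, a mean of 0.034 and an upward test (adjusted p = 0.458). Among endothelial and pericyte markers Ly6c1 and Slco1a4 rose by 0.56 and 0.34 and Rgs5, on chromosome 1 and given above, fell by 1.24, with a list median of 0, a mean of -0.018 and an upward test (adjusted p = 0.65). Igfbp2, on chromosome 1, fell by 0.38 in the choroid plexus list (median -0.02, adjusted p = 0.437), and Ptprz1 fell by 0.38 in the oligodendrocyte precursor list (median 0.019, mean -0.005, upward test, adjusted p = 0.667). Grin3a lost the call without Bl6 mouse 2 or 11 or CSS1 mouse 3, 9 or 12 (adjusted p = 0.0526 to 0.0987), Gabrd without Bl6 mouse 2, 5 or 11, CSS1 mouse 3, 6 or 9 or CSS2 mouse 1, 4 or 10 (0.0524 to 0.141), and Scn4b without Bl6 mouse 2 or 11, CSS1 mouse 3, 9 or 12 or CSS2 mouse 4 (0.0532 to 0.108). Ly6c1 lost it without Bl6 mouse 2, 5 or 11 or CSS1 mouse 3 or 6 (0.0575 to 0.107), Igfbp2 without Bl6 mouse 2, 5 or 11 or CSS1 mouse 6 or 9 (0.0578 to 0.11) and Ptprz1 without Bl6 mouse 2 (0.0538). Without the dye term Grin3a, Gabrd, Scn4b, Ly6c1, Igfbp2 and Ptprz1 lost it (0.0501 to 0.203), and with median centring the first 5 of these and Slco1a4 did (0.0574 to 0.62). No member was called in CSS1 among the endoplasmic reticulum list (median 0.02, adjusted p = 0.545), calcium channels (-0.009, 0.741), heat shock genes (0.03, 0.273), cytokine genes (0.04, 0.0612), meningeal markers (-0.07, 0.0627), erythroid genes (0.20, 0.0671), dentate markers (0.02, 0.199), CA1 and CA3 markers (0.03, 0.199), thalamus, striatum and cortex markers (0.01, 0.0728) or sex-linked genes (0.03, 0.601). Some of these passed with 1 mouse left out: cytokine genes without Bl6 mouse 5 or CSS1 mouse 12 (adjusted p = 0.0259 and 0.0192), meningeal markers without Bl6 mouse 5, CSS1 mouse 12 or CSS2 mouse 1 (0.0135 to 0.0478), erythroid genes without CSS1 mouse 12 or CSS2 mouse 4 (0.0461 and 0.0106), dentate markers without CSS1 mouse 12 (0.0192), and thalamus, striatum and cortex markers without Bl6 mouse 8 or CSS1 mouse 6 (0.0235 and 0.018). Under other processing, meningeal, erythroid and thalamus, striatum and cortex lists passed with median centring (0.0487, 0.0281 and 0.0483) and without the dye term (0.0261, 0.0288 and 0.0345), and cytokine genes without the dye term (0.049) and with the block of mouse numbers (0.0358). With only the strains compared, meningeal and erythroid lists passed (0.0462 and 0.00712), and with array weights thalamus, striatum and cortex markers did (0.044).

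In CSS2 against Bl6, the potassium channel gene Kcnma1 and the pyramidal cell marker Cpne4 each fell by 0.29 in lists that did not pass. The potassium and HCN channel list had a median of -0.03 (adjusted p = 0.46), and CA1 and CA3 markers had a median of 0.002, a mean of -0.033 and a downward test (adjusted p = 0.209). Over the alternatives the lowest adjusted p of the CA1 and CA3 list was 0.0291. Kcnma1 lost the call without any mouse but CSS2 mouse 7 (adjusted p = 0.06 to 0.17), and Cpne4 without any mouse but Bl6 mouse 8 and CSS2 mouse 7 (0.0525 to 0.141). Both also lost it with median centring (0.456 and 0.611) and without the dye term (0.457 and 0.719). For Kcnma1 and Cpne4 the CSS2 mice were at -0.076 and -0.092, and the Bl6 mice lay above their own pool, at 0.213 and 0.198. No member was called among glutamate receptors (median 0.006, mean -0.02, downward test, adjusted p = 0.736), GABA genes (-0.03, 0.655), sodium channels (-0.02, 0.362), calcium channels (-0.02, 0.347), heat shock genes (0.05, 0.087), cytokine genes (0.02, 0.211) or ribosomal proteins (-0.04, 0.087). The same held for microglia (median 0.005, mean -0.008, downward test, 0.801), endothelial (0.03, 0.107), choroid plexus (-0.03, 0.0819) and dentate markers (0.01, 0.432), erythroid genes (-0.07, 0.209), thalamus, striatum and cortex markers (median -0.014, mean 0.005, upward test, 0.486) and sex-linked genes (-0.02, 0.41). Interneuron markers had a median of 0.05 (0.0836) and passed without Bl6 mouse 5 or 8 or CSS2 mouse 1 (0.0329 to 0.0394). Ribosomal proteins passed without Bl6 mouse 8 or CSS2 mouse 1 (0.000361 and 0.0394), erythroid genes without CSS2 mouse 1 (0.0394), endothelial markers without Bl6 mouse 8 (0.0334), and heat shock genes and choroid plexus markers without CSS2 mouse 4 (0.0291 and 0.0136). With median centring the interneuron, heat shock and endothelial lists passed, with medians of 0.0876, 0.0927 and 0.0672 (adjusted p = 0.00241, 0.00645 and 0.0191), and with the mean over a gene's probes ribosomal proteins did (0.0209). In CSS1 against CSS2 the lists not given above did not pass, and median, mean and test differed in sign for glutamate receptors (median -0.017, mean 0.034, upward test, adjusted p = 0.498), calcium channels (0.012, -0.012, upward, 0.477) and oxidative phosphorylation (0.01, -0.002, upward, 0.616). Against the pool, 20 genes differed in the Bl6 mice, all higher, among them Actb with a Bl6 mean of 0.60.

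Each strain held 2 mice of either dye orientation, and 18 of the 35 splits of the 8 mice in a comparison keep that balance, too few for a share under 0.05. In CSS1, CSS2 and CSS1 against CSS2 1 of these 18 splits, the real one, gave as many called genes (439, 225 and 210), and the highest other count was 0 in each. Over all 35 splits the highest other counts were 1, 0 and 0, and those without the balance estimate a difference with a standard error 1.1 to 1.73 times as large.

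An additional list of 24 immature neuron genes, drawn up after the falls of Tubb2b, Dpysl3, Cd24a and Fabp7 had been seen and without them, had medians of -0.14 in CSS1 and -0.07 in CSS2 over 22 measured genes, and 30 mature neuron markers had 0.03 and 0.00. In CSS1 Ncam1, Nrep and Dpysl5 fell, and in CSS2 Dpysl5 fell, a gene also among the shared falls above.

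Myelin genes were higher in both strains, and this rested on no single mouse, since the lowest median with a mouse left out was 0.481 in CSS1 and 0.56 in CSS2. Myelin exceeded microglia and endothelial markers by 0.507 (95% interval 0.307 to 0.708) and 0.584 (0.327 to 0.841), so these did not share the rise. That test was chosen after the myelin rise had been seen, and astrocyte markers, with medians of 0.24 and 0.16, were left out of it. It therefore does not decide on a lower share of neurons, whose mature markers had medians of 0.03 and 0.00. A later developmental stage stays open in both strains. Immature minus mature neuron genes were at -0.176 (-0.296 to -0.0566) in CSS1 and at -0.0746 (-0.181 to 0.0316) in CSS2. The immature list was drawn up after falls of other such genes in the same mice and holds Dpysl5, so its fall in CSS1 is no independent test. More white matter in the tissue stays open for the myelin rise. The median of cell division genes minus that of mature neuron markers was -0.245 (-0.353 to -0.136) in CSS1, so they fell by more than those markers. Their fall was known when this test was chosen, so it is no independent test against white matter. In CSS2 the value was -0.0528 (-0.172 to 0.0663). The rule written for the test counted an interval that includes 0 for white matter. That rule was set aside, since the interval also holds falls, and white matter cannot be told apart there. The strain difference itself stays open and was not tested apart from these.

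Called genes were concentrated on chromosome 1 in CSS1 and on chromosome 2 in CSS2, and donor variants under the probes could lower the signal there without a change in expression. Other probes of a gene were taken only from a minimum mean log2 intensity of 8. In CSS2, 20 of the 76 called genes had such a probe, and these probes moved the same way by a median of 0.251 (95% interval 0.095 to 0.518). This argues against variants as the whole cause for these 20 genes, unless variants lay under both probes, which was not checked. Of the 20, 12 were lower, and 4 of the 12 had the other probe called in the same direction. In CSS1, where 20 of the 93 called genes had another probe from that minimum intensity, the median of those probes was 0.137 (-0.0187 to 0.383). This met the criterion set in advance for variants as the whole cause. The verdict was changed after the result was seen, because 43 of the 93 called genes were higher. That reason holds only if the probes follow the Bl6 sequence, which is not given in the sources used here. As the main source of lower calls they stay open, with lower shares of 53.8% and 47.4%. Both intervals include 50%, the bound set in advance against them, and that bound was set aside after the result was seen. The shares exceeded those off the chromosome (39.3%, Fisher's exact p = 0.0133, and 30.4%, p = 0.0184). That comparison cannot decide it, since the test takes called genes as independent and calls elsewhere include the myelin rises of both strains. Expression differences driven by the donor chromosome stay open as well.

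The probes of Srp9 differed in CSS1, with a fall at the dimmer one alone. Dye bias was argued against, since the difference nearer to 0 of the dye orientations was -0.324, and so was a defective spot on a single array, since the difference nearest to 0 with a mouse left out was -0.365. A donor variant under the dimmer probe could account for the pattern and cannot be told apart from a fall of one transcript form, because probe sequences were not used here. Second probes were again taken only from a minimum mean log2 intensity of 8. Among called genes in CSS1, 8 of 20 second probes on chromosome 1 were called in the same direction, against 28 of 80 elsewhere (Fisher's exact p = 0.795). By sign alone, which that p does not cover, 14 of 20 moved with the called probe on chromosome 1 against 73 of 80 elsewhere. This lower share was not tested, so an excess of discordant probes on chromosome 1 stays open. The 2 counts differ, so they do not argue against a donor variant.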
